A study of Mus musculus with 2 samples.

How the data were processed

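The series was designed to characterise the transcriptional identities of single cells in the mouse habenula. Droplet libraries were made with 3' version 2 chemistry from punches of habenula slices digested with pronase. Per the submitters' processing notes, reads were processed with Cell Ranger 2 against mm10, and the deposited count values are raw UMI counts per gene and barcode. The gene annotation release is not given in the sources used here, and 28339 of the 28692 gene identifiers occur in GENCODE vM21, from which gene positions were taken. Each matrix held 737280 barcodes, so cells were called here.

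The filters, classes, gene lists, comparisons and naming rule below were fixed before the data were examined, except where stated. A cell was a barcode with at least 1000 UMIs, 500 to 6000 detected genes and at most 20% of UMIs from mitochondrially encoded genes. This gave 5129 cells in control and 4840 in foot shock, after 64 and 189 barcodes over the mitochondrial limit were left out. Doublets were called per library with Scrublet in scanpy at an expected rate of 0.08 and its automatic threshold, which removed 249 control cells (4.85%) and 69 foot shock cells (1.43%). Kept cells held 67.6% and 64.5% of all UMIs, with median mitochondrial shares of 4.90% and 5.06%. Free RNA was measured as the summed counts of barcodes with 10 to 100 UMIs, 74374 in control and 94619 in foot shock.

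Both libraries were clustered together without integration. Counts per 10000 were log-transformed, and 2000 variable genes, 30 principal components, 15 nearest neighbours on a shared-neighbour graph and Leiden resolution 1.0 were used. Genes of the response and habenula lists, mitochondrial, ribosomal protein and hemoglobin genes were kept out of the features. A cluster took the name of a cell type when it held at least 3 of its markers, a marker being held when found in at least 10% of its cells and at 33.3% or more of the highest cluster. Habenula names also required Pou4f1 at 1 count per 10000 or more, a threshold set after the data were seen. This gave 30 clusters. Of 28 that were checked, 0 had more markers of another class than of their own among their 10 leading genes. Some clusters had no marker of either kind there, so the check could not fail for them. Clusters with markers of 2 unrelated classes were named mixed and left out, 12 cells in control and 82 in foot shock, leaving 4868 and 4689 cells. LHb-like and MHb-like neurons were clustered again among themselves with the same settings.

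For foot shock against control, counts were summed per class and library in classes with at least 50 cells in each library and scaled to the class total. Levels carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals. Log2 ratios of lists used a prior count of 0.5. The response lists were rapid immediate early genes (30 genes), delayed activity-regulated genes (17), glucocorticoid-induced genes (15), heat shock genes (10), microglial ex vivo activation genes (10), interferon-induced genes (10), integrated stress response genes (8) and mitochondrially encoded genes (13). A member was measured with at least 20 UMIs over both libraries, and the list median was placed among 10000 random lists matched on expression in 20 bins. The habenula lists were nicotinic receptor subunits (9), receptors for opioids, monoamines and peptides (22), glutamate and GABA receptor subunits (16), pacemaking and burst channels (14) and neuropeptides and granule proteins (17). Shares of cells with an immediate early gene UMI were computed with each cell thinned to 1000 UMIs, as the mean over all possible draws.

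By the naming rule, rapid immediate early genes with at least 20 UMIs could be named in LHb-like and MHb-like neurons, with the 10 genes furthest in each direction among genes with at least 100 UMIs whose level in the class was above that in free RNA, in the library where the gene was higher. In other classes the rule named 3 genes in each direction and the list members with the largest and smallest ratio. Between medial and lateral neurons it named list members and 10 further genes in each direction that were neither features nor markers, and for clusters up to 3 leading genes found in at least 25% of their cells. Lists of epithelial, Y-linked and proliferation genes were written after the clusters were seen. Of 17 alternative settings, 14 were fixed beforehand and 3 were added after the data were seen.

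The intervals were tested on data simulated with counting error alone, which is what the intervals assume. The test thus checks the computation and not any spread between cells or libraries. Of 200 simulated genes with set ratios, 191 had an interval that held the set ratio and 171 an interval without 1. Of 1000 simulated class shares, 958 were held by their interval. Simulated lists set at ratios of 1.1, 1.5 and 2 gave medians of 0.17, 0.45 and 0.86, so medians near 0.10 could not be separated from no difference. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors.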

Results

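Single cells of the habenula were profiled by droplet RNA sequencing in adult male C57BL/6 mice aged 50 to 55 days. The habenula is a small paired structure of the epithalamus with a medial part (MHb) and a lateral part (LHb). The series holds 2 libraries, 1 per group, each from the pooled habenula tissue of 4 mice. Control mice were taken from the home cage, and mice of the foot shock group alone had also spent 10 min per day in the shock chamber on 7 earlier days. Mice of the foot shock group received 30 shocks of 0.3 mA and 1 s during a session of 60 min, and tissue was collected straight after the session, in the presence of blockers of transcription, translation and neuronal firing. The values are unique molecular identifier (UMI) counts per gene and barcode. The control library held 23095501 UMIs and the foot shock library 22189951. After filtering, 4880 control cells with a median of 2416.5 UMIs and 1192 genes were kept, and 4771 foot shock cells with a median of 2698 UMIs and 1300 genes. There are no replicates in either group, so no test between groups was made, and every interval covers counting error only. Levels are given as CPM, the UMIs of a gene scaled to the total of its class and library. In habenula neurons, the genes named from response lists other than the rapid immediate early list were chosen after their values were seen, and so were most of the list members named in glia.

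Neurons of the MHb, neurons of the LHb and oligodendrocytes were the most abundant classes in both libraries. MHb-like neurons, which hold the cholinergic and tachykinin-expressing cells of the structure, made up 25.0% of control cells (exact Clopper-Pearson 95% interval 23.8 to 26.3%) and 35.2% of foot shock cells (33.8 to 36.6%). LHb-like neurons made up 20.7% (19.6 to 21.9%) and 18.0% (16.9 to 19.1%). Astrocyte-like cells made up 11.8% of control cells (10.9 to 12.8%) and 3.16% of foot shock cells (2.67 to 3.70%), and oligodendrocyte-like cells made up 22.2% and 17.7%. Oligodendrocyte precursor-like cells were 5.01% of the control library (4.42 to 5.66%) and 2.18% of the foot shock library (1.78 to 2.63%). Microglia-like cells were 2.36% and 1.49%, committed precursor-like cells 1.89% and 1.43%, and mural-like cells of the vessel wall 1.11% and 1.30%. Endothelial-like, fibroblast-like, ependymal-like and macrophage-like cells each made up less than 1.5% of either library. Thalamus-like neurons, led by the genes C1ql3, Ramp3 and Gbx2, were 2.69% of control and 1.24% of foot shock cells. Other neurons, which lacked the habenula transcription factor Pou4f1 at the level required for a habenula name, were 4.93% and 4.35%. No cluster took the name of GABAergic or hippocampal neurons, choroid plexus epithelium, lymphocytes, neutrophils, erythrocytes or pinealocytes. Among neurons alone, MHb-like cells were 46.9% in control and 59.9% in foot shock, and LHb-like cells were 38.8% and 30.6%.

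Keratin-expressing cells were found in the foot shock library alone. They formed 2 clusters of 317 and 186 cells, led by the epithelial genes Cldn3, Wfdc18 and Wfdc2 in the larger and by Wnt6, Igfbp2 and Krt14 in the smaller. Together they made up 10.7% of that library (9.86 to 11.6%), and 0 of 4868 control cells, which allows a share of up to 0.0757%. Left in the total, they lower the share of every other class in the foot shock library, and without them MHb-like neurons made up 39.4% and LHb-like neurons 20.1%. The shares of astrocyte-like cells, MHb-like neurons, LHb-like neurons and oligodendrocyte-like cells depended on the lowest depth accepted for a cell. Astrocyte-like cells had a median of 1181.5 UMIs in control and 1185 in foot shock, close to the minimum of 1000, and with a minimum of 500 UMIs their shares were 18.0% and 13.4%.

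**Figure D1:**
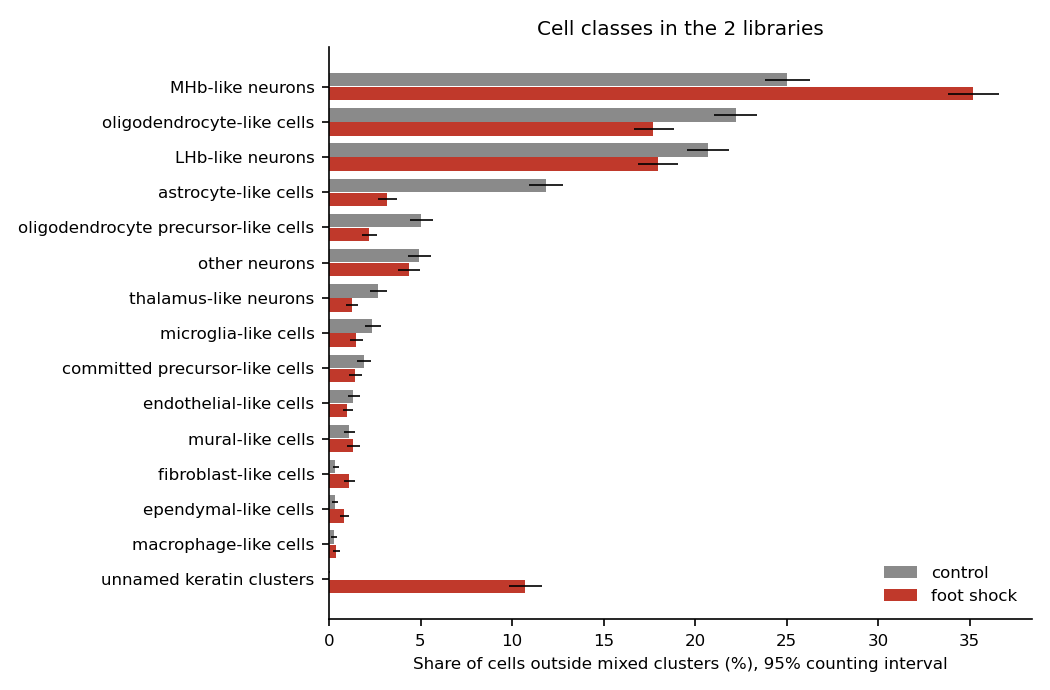
Share of cells (%) in each cell class, control in grey and foot shock in red, with exact 95% binomial intervals as black lines. MHb-like neurons reach 25.0% and 35.2%, astrocyte-like cells 11.8% and 3.16%, and the keratin clusters 0% and 10.7%.

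**Figure D2:**
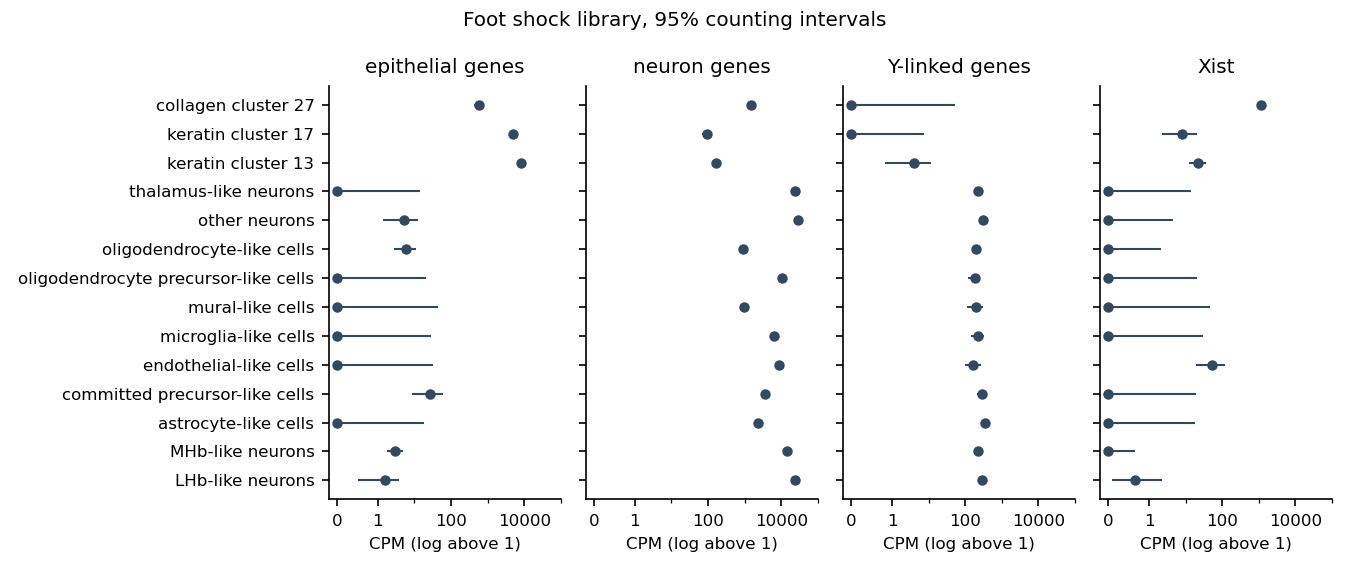
Summed CPM (linear below 1 and log above) of epithelial, neuron and Y-linked genes and of Xist in classes and clusters of the foot shock library, each a point with its exact 95% Poisson interval. Keratin clusters 13 and 17 stand at 7945 and 4881 CPM of epithelial genes.

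The comparison of foot shock with control within LHb-like neurons asks which genes differed in the lateral habenula after an aversive session. Transcripts of the activity-induced transcription factors Fos, Egr1 and Jun were higher in the foot shock library. Fos (ENSMUSG00000021250, mm10 chromosome 12, 85473890 to 85477273) was at 8.50 CPM in control and 27.7 CPM in foot shock, a ratio of 3.26 (exact conditional binomial 95% interval 2.19 to 4.93). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) was at 14.01 and 39.0 CPM, a ratio of 2.78 (2.03 to 3.85). Jun (ENSMUSG00000052684) was at 25.3 and 49.9 CPM, a ratio of 1.98 (1.54 to 2.55). The rest of the rapid immediate early gene list differed less. Sik1, a salt-inducible kinase, had a ratio of 1.37 (1.08 to 1.74), Junb had 1.47 with an interval that held 1 (0.759 to 2.86), and Arc, a regulator of synaptic AMPA receptors, was at 7.58 and 8.05 CPM. Over the 16 measured members of that list, 3 had a ratio of at least 1.5 and 0 were lower by as much, and the median log2 ratio was 0.10. That median lay at percentile 95.65 of random lists matched on expression, and simulated counts with no difference between the libraries gave a like median of 0.10 at percentile 92.59.

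Genes of delayed activity programmes went both ways in LHb-like neurons. Pcsk1, which cleaves prohormones, was at 5.28 CPM in control and 15.1 CPM in foot shock (ratio 2.86, 1.71 to 4.94), and the nuclear receptor Nr4a2 was at 287 and 426 CPM (1.48, 1.37 to 1.60). The neurotrophin Bdnf was lower in the foot shock library, at 28.0 and 16.4 CPM (0.586, 0.414 to 0.819). The median of the 12 measured members was 0.04. Heat shock genes had a median log2 ratio of 0.37 over 9 measured members at percentile 100 of the random lists, and of 0.18 over members with at least 100 UMIs. The inducible chaperones Hspa1a and Hspa1b, which are close paralogs, had ratios of 2.80 (1.74 to 4.63) and 2.96 (1.28 to 7.43), and their partner Dnajb1 had 1.55 (1.33 to 1.81). Both paralogs stood below their free RNA level in the foot shock library, at 17.4 against 23.1 CPM and 6.12 against 7.26 CPM. The constitutive chaperone Hspa8 was lower in foot shock (0.906, 0.848 to 0.968). Glucocorticoid-induced genes had a median of 0.25 over 10 members, led by Nfkbia at 1.62 (1.07 to 2.45) and Sgk1 at 1.54 (1.03 to 2.30). This median was -0.030 after an ambient share was subtracted. The interferon-induced list had a median of 0.21 over 3 members, the integrated stress response list -0.05 over 7, the mitochondrially encoded genes 0.13 over 13, and Cd83 alone was measured of the microglial list, at -0.37.

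By rank, the genes furthest higher in LHb-like neurons of the foot shock library included Vps8, a subunit of an endosomal tethering complex, at 489 and 1477 CPM (ratio 3.02, 2.87 to 3.18). Vps8 was also higher in the free RNA of the foot shock library, at 414 and 1025 CPM. The ATP-gated channel P2rx4 had a ratio of 2.54 (1.99 to 3.25), Lrrc17 had 2.37, the long noncoding RNA gene A330069E16Rik 2.25, and the deadenylase subunit Cnot3 2.17. Mctp1 and Sema3d, at 2.07 and 2.01, were among the leading genes of a subcluster that held 3.87% of LHb-like neurons in control (2.77 to 5.25%) and 7.60% in foot shock (5.90 to 9.60%). Popdc3 had a ratio of 2.05. On the lower side stood Gm12027 at 46.9 and 14.5 CPM (0.309, 0.219 to 0.429), the synaptic membrane protein gene Syndig1 at 0.335, the purinergic receptor P2ry1 at 0.359, the survival factor Bcl2 at 0.367 and the cation channel Trpc5 at 0.429. Ccnd1, Sept1, Tmem169, Nup210 and Cdyl had ratios from 0.458 to 0.513. Gm12027 was among the leading genes of another LHb-like subcluster, which held 29.5% of the class in control and 18.6% in foot shock.

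In MHb-like neurons, asked the same question, Egr1 and Fos were again higher in the foot shock library, and so were Sik1, Arc and Jun. Egr1 was at 5.35 CPM in control and 17.2 CPM in foot shock (ratio 3.22, 2.08 to 5.12), and Fos was at 12.3 and 23.9 CPM (1.94, 1.43 to 2.67). Sik1 was at 35.5 and 58.5 CPM (1.65, 1.37 to 1.99), Arc at 12.7 and 20.6 CPM (1.62, 1.18 to 2.23), and Jun had a ratio of 1.69 (1.20 to 2.40). These 5 were the members with a ratio of at least 1.5 among 18 measured, 0 were lower by as much, and the list median was 0.20 at percentile 99.94. Btg2, Fosb, Nr4a1, Dusp5 and Fbxo33 had ratios between 0.945 and 1.17, with intervals that held 1. Free RNA of the foot shock library held Fos at 72.8 CPM and Egr1 at 23.1 CPM, against 15.5 and 7.76 CPM in control.

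Heat shock genes were higher in MHb-like neurons of the foot shock library, with a median log2 ratio of 0.34 over 9 members at percentile 100. Hspa1a (ENSMUSG00000091971) was at 5.95 and 23.4 CPM (3.93, 2.63 to 6.05), Hspa1b at 1.19 and 12.8 CPM (10.8, 4.72 to 30.3), and Dnajb1 at 58.1 and 124 CPM (2.14, 1.87 to 2.46). Glucocorticoid-induced genes had a median of 0.31 over 10 members, with the mTOR inhibitor Ddit4 at 2.40 (1.64 to 3.58) and the metallothionein Mt2 at 1.98 (1.71 to 2.29). Both stood below their free RNA level in either library, Mt2 at 105.6 CPM in the class against 1357 CPM in free RNA. Sgk1, of the same list, was seen without thinning in 0.410% of control MHb-like neurons (0.133 to 0.955%) and 2.36% in foot shock (1.69 to 3.22%). Free RNA of the foot shock library held Sgk1 at 104 CPM. The delayed activity list had a median of 0.03 over 12 members, the interferon list -0.19 over 4, the stress response list -0.01 over 7 and the mitochondrial genes 0.09 over 13, and Cd83, the single measured gene of the microglial list, was at 0.27. By rank, Sag, which encodes an arrestin of photoreceptor cells, was at 11.9 and 24.1 CPM (2.02, 1.48 to 2.79), and Swt1, Slmo1, the SUMO protease Senp5, 4930532G15Rik, Dhx8, Ube2v1 and Ptcra had ratios from 1.73 to 1.96. Lower in foot shock were Galntl6 at 25.6 and 11.1 CPM (0.433, 0.315 to 0.589), the calcium-activated potassium channel Kcnn3 at 37.3 and 19.5 CPM (0.523, 0.410 to 0.665), the synaptic adaptor Apba1 at 335 and 181 CPM (0.542, 0.501 to 0.586) and the orphan receptor Gpr26 at 136 and 74.9 CPM. Sap30l, Cyp2u1, Cebpb, Myadm, Pde3b and Gm26699 had ratios from 0.484 to 0.545.

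Egr1 UMIs were found in a larger share of LHb-like neurons in the foot shock library. With each cell thinned to 1000 UMIs, Egr1 was seen in 1.06% of control LHb-like neurons (0.546 to 1.94%) and 3.04% in foot shock (2.03 to 4.49%), and Fos in 0.611% (0.219 to 1.29%) and 1.84% (1.09 to 3.07%). In MHb-like neurons Egr1 was seen in 0.479% (0.181 to 1.07%) and 1.53% (0.983 to 2.23%), Fos in 1.23% (0.690 to 2.02%) and 2.33% (1.63 to 3.15%), and Arc in 1.17% (0.629 to 1.92%) and 2.03% (1.43 to 2.87%), with overlapping intervals for each of these 3 genes. Oligodendrocyte-like cells, which served as background, showed Egr1 in 0.0578% and 0.255% and Fos in 0.391% and 0.473%. Median depths before thinning were 4256 and 3606 UMIs in LHb-like neurons, 4211 and 3462 in MHb-like neurons and 2067 and 1846 in oligodendrocyte-like cells. Oligodendrocyte-like cells gave no background for Arc, which was seen in 4.23% and 2.61% of them and stood at 42.1 and 24.3 CPM, above its free RNA level of 8.87 and 10.6 CPM. In microglia-like cells, with median depths of 1485 and 1383 UMIs, Arc was seen in 0%, with upper limits of 3.16% and 5.13%. Without thinning, Egr1 was seen in 4.37% and 8.08% of LHb-like neurons and in 2.21% and 4.42% of MHb-like neurons.

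**Figure D3:**
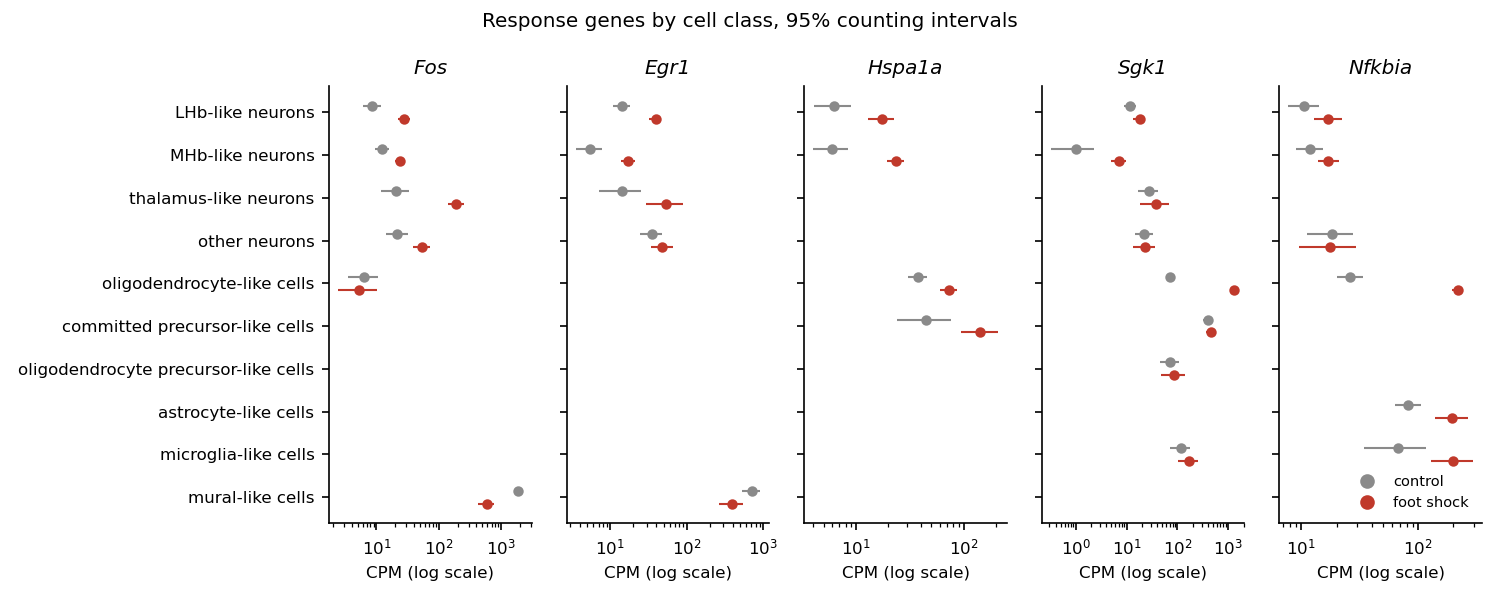
CPM (log axis) of Fos, Egr1, Hspa1a, Sgk1 and Nfkbia by cell class, control in grey and foot shock in red, each point with its exact 95% Poisson interval; a class with fewer than 20 UMIs of a gene has no point. Sgk1 in oligodendrocyte-like cells stands at 71.2 and 1312 CPM, while Fos is higher in foot shock in neurons and lower in mural-like cells.

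In oligodendrocyte-like cells, the myelinating glia, genes induced by glucocorticoids were far higher in the foot shock library. Sgk1, a serum and glucocorticoid regulated kinase (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903), was at 71.2 CPM in control (60.8 to 82.7) and 1312 CPM in foot shock (1258 to 1368), a ratio of 18.4 (15.8 to 21.7). Nfkbia, an inhibitor of NF-kB, had a ratio of 8.32 (6.34 to 11.1), and the cell cycle inhibitor Cdkn1a 5.45 (3.45 to 8.92). The clock gene Per1 had 4.97 (2.76 to 9.48), Ddit4 4.11 (3.48 to 4.88), Mt2, below its free RNA level in both libraries, 3.16 (2.60 to 3.87), the receptor co-chaperone Fkbp5 2.49 (1.75 to 3.56) and Klf9 1.91 (1.67 to 2.20). Of 14 measured members of the list, 9 were at least 1.5 times higher and 2, Plin4 and Bcl6, were lower by as much, and the median log2 ratio was 1.12 at percentile 100. The mitochondrial list had a median of 0.03, the heat shock list 0.28 at percentile 99.97 and the delayed activity list, which contains Cdkn1a, 0.56 at percentile 99.98. The rapid immediate early list had a median of -0.28 over 10 members, the interferon list -0.32 over 2 and the stress response list -0.33 over 4. Lower in foot shock by rank were the transcriptional repressor Bhlhe41 at 264 and 79.9 CPM (0.302, 0.249 to 0.364), Gm26699 at 0.339 and Nfe2l3 at 0.385. TMM scaling would move every log2 ratio in this class by 0.10. Thinned to 1000 UMIs, Sgk1 was seen in 6.98% of control oligodendrocyte-like cells (5.50 to 8.62%) and 69.5% of foot shock cells (66.2 to 72.6%). In MHb-like neurons the share was far smaller but also higher in foot shock, at 0.0924% (0.00208 to 0.456%) and 0.663% (0.333 to 1.19%), with overlapping intervals.

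Some other glia shared parts of this difference, and immediate early genes differed between classes in direction. In astrocyte-like cells the glucocorticoid list had a median of 1.04 over 8 members, with Cdkn1a at 3.51 (1.92 to 6.40), Per1 at 2.74 (1.31 to 5.63) and Mt2 at 2.41 (2.28 to 2.55). In oligodendrocyte precursor-like cells that median was 0.28 over 6 members and in committed precursor-like cells 0.22 over 5. In microglia-like cells it was 1.62 over 6 members, with Mt2 at 16.7 and 373 CPM from 3 and 47 UMIs (22.4, 7.20 to 112) and Fkbp5 at 6.78 (2.25 to 27.4). Mt2 in this class was below its free RNA level of 822 CPM in control and 1357 CPM in foot shock. The rapid immediate early list had a median of 0.53 in microglia-like cells over 8 members, at percentile 94.96, with the transcription factor Klf2 at 2.86 (1.15 to 7.71) and 6 of the 8 intervals holding 1. Over 2 members in committed precursor-like cells it had a median of 0.30, at percentile 77.01. The microglial ex vivo activation list had 1 measured member in microglia-like cells, the chemokine Ccl4, at 111 CPM from 20 UMIs in control and 0 UMIs in foot shock, with an upper limit of 29.3 CPM. In mural-like cells the rapid immediate early list was lower in foot shock, with a median of -1.12 over 10 members at percentile 0. There Fos was at 1887 and 585 CPM (0.310, 0.219 to 0.431) and Junb at 1949 and 524 CPM (0.269, 0.187 to 0.379). The same list had a median of -0.88 in astrocyte-like cells over 6 members, although Gadd45g was higher at 2.52 (1.72 to 3.68), and of -0.71 in oligodendrocyte precursor-like cells over 3. Neat1, Spry2 and Notch2 were lower in foot shock astrocyte-like cells, at 0.145, 0.152 and 0.228. In committed precursor-like cells the heat shock list had a median of 0.74 over 9 members, led by Dnajb1 at 4.50 (2.50 to 8.50). Neuron transcripts were more abundant in several foot shock glial classes, the noncoding RNA Meg3 being at 949 and 5139 CPM in microglia-like cells, 482 and 1692 CPM in astrocyte-like cells and 409 and 2955 CPM in committed precursor-like cells. UMIs of neuron genes were spread unevenly over the cells of the foot shock library. They averaged 11.2 per microglia-like cell and 10.1 per committed precursor-like cell, with a median of 1 in both classes. Actb was lower in microglia-like cells (0.377) and in mural-like cells (0.288).

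Medial and lateral habenula neurons were compared within each library to describe which receptors, channels and peptides set them apart. Nicotinic receptor subunits were much higher in MHb-like neurons. Chrna3 (ENSMUSG00000032303, chromosome 9, 55010111 to 55026562) was at 370 CPM in MHb-like and 7.12 CPM in LHb-like neurons of the control library, a ratio of 52.0 (36.5 to 76.7), and at 380 and 9.34 CPM in the foot shock library. Chrnb4 had ratios of 32.3 and 23.1 and Chrnb3 22.6 and 16.8, and the acetylcholine vesicle transporter Slc18a3 had 41.2 and 45.2. Tac2, the neurokinin B precursor, was at 577 and 13.3 CPM in control and 599 and 27.7 CPM in foot shock. The cannabinoid receptor Cnr1 (9.36 and 5.31), the large-conductance potassium channel Kcnma1 (5.15 and 4.83) and the GABA-B receptor subunit Gabbr2 (3.88 and 3.51) were also higher in MHb-like neurons of the control and foot shock libraries.

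LHb-like neurons carried more transcripts of several monoamine and muscarinic receptors and of the channels Cacna1i and Kcnc1. The muscarinic receptor Chrm2 (ENSMUSG00000045613, chromosome 6, 36388084 to 36528414) was at 127.5 CPM in LHb-like and 1.59 CPM in MHb-like neurons of the control library, and at 109.8 and 1.93 CPM in the foot shock library. The serotonin receptor Htr2c was at 469.6 and 10.3 CPM in control and 507 and 14.8 CPM in foot shock. The T-type calcium channel Cacna1i was at 159 and 20.0 CPM in control and 122 and 24.6 CPM in foot shock, and the potassium channel Kcnc1 was at 114 and 1.39 CPM, then 86.3 and 1.23 CPM. The dopamine receptor Drd1 was at 11.7 and 6.12 CPM in LHb-like neurons, with 0 UMIs in MHb-like neurons of either library.

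By list, 5 of 6 measured nicotinic subunits were at least 2 times higher in MHb-like neurons of both libraries, with medians of 4.51 in control and 4.04 in foot shock, and Chrnb2 was near equal. Of 17 receptors for opioids, monoamines and peptides, 4 were higher by as much in MHb-like and 9 in LHb-like neurons, with medians of -1.14 and -1.35. These turned to 1.13 and 0.39 when only members with at least 100 UMIs were counted, which drops Drd1, Oprk1 and Htr1b among others. Of 16 glutamate and GABA receptor subunits, 2 were higher in MHb-like and 7 in LHb-like neurons (medians -0.81 and -0.86). Of 14 pacemaking and burst channels the counts were 1 and 7 (medians -1.05 and -1.23), and of 13 neuropeptides and granule proteins 3 and 6 (medians -1.03 and -0.64). TMM scaling would shift these log2 ratios by 0.15 in control and 0.13 in foot shock. Some listed genes also helped to name the classes, so their difference is partly set by the naming, among them Chrna3, Chrnb4, Tac2 and Htr2c. Without such genes the nicotinic medians were 3.29 and 2.99. Of the 14 remaining receptors for opioids, monoamines and peptides, 4 were higher in MHb-like and 7 in LHb-like neurons (medians -0.94 and -1.05). Of the 15 remaining glutamate and GABA receptor subunits the counts were 2 and 6, and of the 7 remaining neuropeptides and granule proteins 0 and 4 (medians -1.27 and -1.26). By rank, genes outside the lists included Tpbgl, Rspo4 and Copz2 on the medial side, at ratios of 89.1, 60.7 and 123 in control and 40.7, 41.5 and 42.3 in foot shock. The Copz2 ratio in control has an interval of 21.8 to 4910, since its LHb-like level there was 0.230 CPM. On the lateral side stood Ajap1, at 44.8 CPM against 0.397 CPM in control, the metabotropic glutamate receptor Grm7 at 42.0 against 0.397 CPM and the adhesion receptor Adgrl2 at 66.4 against 0.793 CPM.

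**Figure D4:**
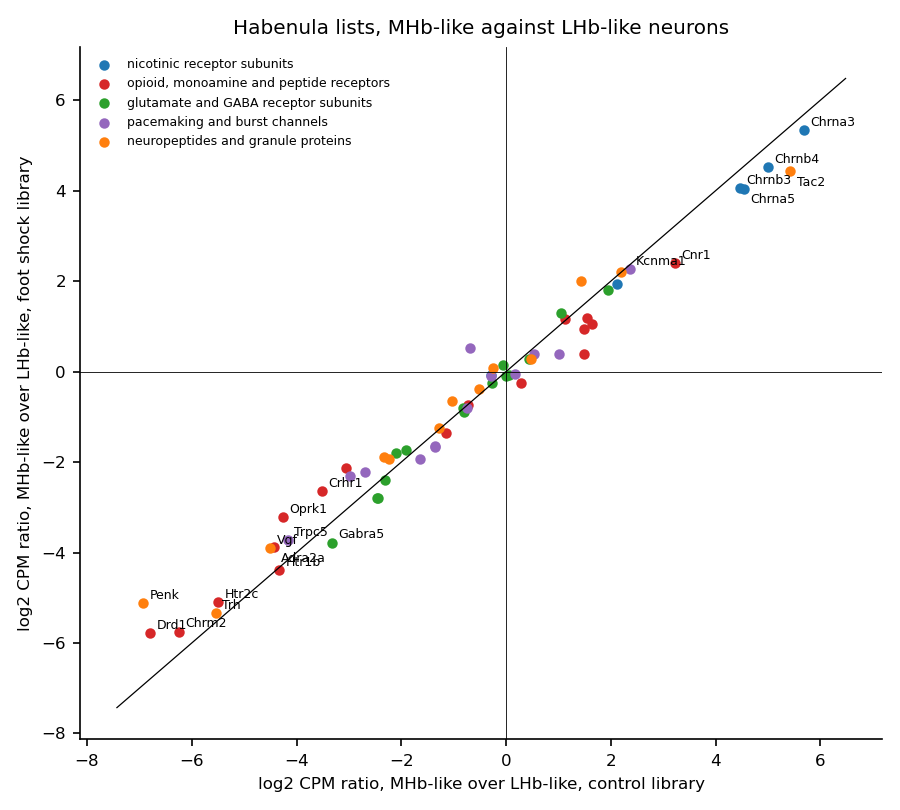
Log2 ratio of CPM in MHb-like over LHb-like neurons for most measured members of the habenula lists, control library on the horizontal and foot shock library on the vertical axis, each point a gene and the diagonal marking equal ratios. The nicotinic subunits Chrna3 (5.68 and 5.33) and Chrnb4 (5.00 and 4.52) lie at one end and Chrm2 (-6.24 and -5.75) at the other.

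Habenula neurons fell into 15 subclusters, each with cells of both libraries. The subclusters named here were chosen after their values were seen. In the LHb-like subcluster led by Chrm2, 9330158H04Rik and Adgrl2, which made up 18.8% of the class in control and 20.1% in foot shock, Egr1 was at 5.86 and 70.7 CPM (ratio 12.1, 4.87 to 38.6), Fos at 3.51 and 41.1 CPM from 3 and 32 UMIs (11.7, 3.66 to 59.7) and Jun at 21.1 and 50.1 CPM (2.38, 1.33 to 4.41). The rapid list as a whole had a median of 0.13 over 8 members in that subcluster, at percentile 82.23 of random lists. In the LHb-like subcluster led by Megf11, Cacna2d1 and Gabrg1, Egr1 was at 31.7 and 29.5 CPM (0.930, 0.462 to 1.77). Among MHb-like neurons, the subcluster led by 2600014E21Rik, Lsp1 and Synpr had Egr1 at 5.21 and 34.3 CPM (6.58, 2.82 to 18.7), Fos at 4.34 and 26.9 CPM (6.19, 2.44 to 20.1) and a rapid list median of 0.45 over 12 members. Differences between subclusters were not tested.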

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

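All tests of the keratin cells were chosen after the cells were seen.

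Keratin-expressing cells numbered 503 in the foot shock library and 0 in control. Epithelial genes, among them Krt8 and Epcam, stood at 7945 and 4881 CPM in their 2 clusters, against 1.99 CPM in control (1.35 to 2.83) and 4.50 CPM in foot shock brain classes (3.41 to 5.84). The latter leaves out the 45 cells of a fibroblast-like cluster led by Timp1, and with them it was 7.86 CPM. Of its 57 epithelial UMIs, 16 were in the 38 ependymal-like cells, and without ependymal-like cells the levels were 1.93 CPM (1.31 to 2.76) and 3.29 CPM (2.36 to 4.46). Proliferation genes stood at 1811 and 1257 CPM. The mice were male, yet Y-linked genes such as Ddx3y stood at 2.43 CPM in these cells (0.502 to 7.11), against 181 to 350 CPM in the 10 compared brain classes of the foot shock library. Xist, the RNA of the inactive X chromosome, had 20 UMIs in the keratin cells, found in 1.39% of them (0.561 to 2.85%).

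Contaminating cells loaded with the brain suspension in the same droplet run would carry its free RNA, but 4.77% of keratin cells had a neuron-gene UMI (3.08 to 7.02%), below the 16.4% of barcodes with 31 to 100 UMIs, which argues against it. Molecules of a separate run read in both libraries are also argued against: 13.2% of keratin barcodes had 10 UMIs or more in control (10.3 to 16.5%), near the 11.7% of brain-cell barcodes, with 0 epithelial UMIs. Molecules of a separate run read in the foot shock library alone stay open, although that explanation needs equal epithelial levels in brain cells of both libraries. The share of brain cells with an epithelial UMI was 1.11% in foot shock (0.814 to 1.48%) and 0.575% in control (0.383 to 0.830%), a ratio of 1.93 with overlapping intervals. The CPM intervals overlap without ependymal-like cells, but with them they lie apart (3.41 to 5.84 against 1.35 to 2.83). Free RNA barcodes of 31 to 100 UMIs showed no epithelial excess in foot shock. They held 31.7 CPM (25.9 to 38.3) against 36.3 CPM in control (30.2 to 43.2). Other ranges went both ways. Barcodes of 10 to 20 and 21 to 30 UMIs were lower in foot shock (204 and 46.8 against 1366 and 527 CPM). Barcodes of 1 to 9 UMIs, and those between 100 UMIs and the cell minimum, were higher (960 and 363 against 192 and 8.94 CPM). Overlap of separate intervals does not show that levels are equal, so these values do not decide the question. An origin in the dissected mice would be a hypothesis that the low Y-linked level of 2.43 CPM speaks against.

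A fibroblast-like cluster led by Timp1, Col3a1 and Col6a3 held 45 foot shock cells and 0 control cells. It had Xist at 1158 CPM from 83 UMIs, Y-linked genes at 0 UMIs, and epithelial genes at 600.2 CPM. Neuron-gene UMIs were in 68.9% of its cells (53.4 to 81.8%), unlike the keratin cells. Oligodendrocyte-gene UMIs were in 2.22% of its cells (0.0562 to 11.8%) and in 8.35% of keratin cells. Among foot shock barcodes with 31 to 100 UMIs they were in 16.5%, so the 2 gene sets do not give the same picture of free RNA in this cluster. Foot shock macrophage-like cells also held Xist, at 534 CPM, with Y-linked genes at 71.2 CPM (8.63 to 257). The origin of both was not tested.

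Epithelial genes stood at 1366 CPM in control barcodes of 10 to 20 UMIs and at 36.3 CPM in those of 31 to 100 UMIs. The former came from 75 UMIs in 68 of 3911 barcodes, with 0 at barcodes of keratin cells.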

How the results depend on the processing

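No paired analysis was possible because each group is 1 pooled library. Of 863 values over 17 settings, 758 stayed, 102 moved (56 up, 46 down) and 3 reversed. The equal doublet share, the shares without keratin clusters and the setting that counts neurons with little Pou4f1 as LHb-like were added after the data were seen, and the last applies only to LHb-like results and medial against lateral. The single-gene ratios of foot shock over control that were recomputed, among them Fos, Egr1 and Sgk1, stayed inside their intervals. The cause of a move was not tested.

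With a minimum of 2000 UMIs, 3013 control and 3094 foot shock cells were kept and 85 control doublets removed, and with 500 UMIs 249 foot shock doublets. There is no doublet count with doublets kept, no list minimum for single genes, and no share at 2000 UMIs for astrocytes, microglia, mural cells and oligodendrocyte precursors.

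LHb-like neurons in control made up 25.1% at 2000 UMIs, 24.0% with doublets kept, 23.9% at resolution 0.5, 15.7% at 2.0 and 25.6% with little-Pou4f1 neurons. In foot shock they made up 16.8% at 500 UMIs, 21.4% at 2000, 21.4% with doublets kept, 21.6% at resolution 0.5, 14.7% at 2.0, 19.5% with the lists among the features, 20.1% without keratin clusters and 22.3% with little-Pou4f1 neurons. MHb-like neurons made up 23.4% (500) and 39.1% (2000) in control, and 28.7% (500), 47.1% (2000), 37.0% (mitochondrial limit 10%) and 39.4% (no keratin clusters) in foot shock. Astrocyte-like cells made up 18.0% (500) and 10.8% (lists among features) in control, and 13.4% and 2.53% in foot shock. Oligodendrocyte-like cells made up 18.9% (500) and 24.2% (limit 10%) in control, and 14.97% (500), 11.1% (2000) and 19.9% (no keratin clusters) in foot shock.

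With free RNA subtracted, the glucocorticoid median reversed to -0.030 in LHb-like neurons and was 0.86 in oligodendrocyte-like cells. The heat shock median in LHb-like neurons was 0.18 with a list minimum of 100 UMIs. That minimum also reversed the medians of opioid, monoamine and peptide receptors, to 1.13 in control and 0.39 in foot shock. With a prior count of 5 the nicotinic medians were 3.16 and 2.89. Without thinning, Egr1 was seen in 4.37% and 8.08% of LHb-like and in 2.21% and 4.42% of MHb-like neurons, as deeper cells yield more UMIs.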

Other observations

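All tests below except the one by mitochondrial share were chosen after the results were seen.

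Sgk1 was higher in the foot shock library in each of the 3 oligodendrocyte-like clusters. The ratio was 22.01 (17.7 to 27.8) in the cluster led by Ptgds, Opalin and Mal, 13.2 (10.2 to 17.2) in that led by Anln, Hapln2 and Pmp22, and 16.6 (10.1 to 29.0) in that led by Ttyh2, Bmp2k and Mtmr2. In committed precursor-like cells Sgk1 was at 392.2 and 458 CPM, a ratio of 1.17 (0.874 to 1.56).

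In thalamus-like neurons Fos was at 20.7 CPM in control and 189 CPM in foot shock, a ratio of 9.11 (5.10 to 17.1), and the neurotrophin Bdnf at 77.7 and 170 CPM (2.19, 1.45 to 3.27). The rapid list as a whole had a median of -0.04 there over 8 members, 3 at least 1.5 times higher and 2 lower by as much. In other neurons Fos had a ratio of 2.51 (1.4997 to 4.29), and the rapid list median was 0.62 over 9 members.

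Receptors and peptides marked the same habenula subclusters in both libraries for 38 of 55 genes. Somatostatin (Sst) was highest in 1 mostly LHb-like subcluster, at 486 CPM in control and 460 CPM in foot shock, and Chrm2 in another, at 411 and 290 CPM. The peptide gene Cck was at 1052 and 981 CPM in a mostly MHb-like subcluster. The opioid receptor Oprm1 was highest in different subclusters in the 2 libraries.

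Higher Fos and Egr1 in foot shock neurons could come from free RNA, but after the most free RNA that Junb allows was taken out, the lowest lower limit among the 4 ratios was 1.14, which argues against it. A stronger immediate early gene response to dissociation in every class is argued against by the rapid list median of -1.12 in mural-like cells. The rapid list median was 0.53 in microglia-like cells (percentile 94.96 of random lists) and 0.30 in committed precursor-like cells (77.01), neither set apart from random lists. Thinned to equal depth, Fos was seen in 0.664% of control microglia-like cells (0.0220 to 4.75%) and 8.85% in foot shock (3.21 to 17.7%). These intervals overlap, but without thinning they lie apart, at 1.74% (0.211 to 6.14%) and 15.7% (8.11 to 26.4%). Egr1 was near equal in this class, at 4.37% and 4.96% thinned. Higher Fos was thus not confined to neurons, although few microglia-like cells held it. The heat shock list had a median of 0.24 at percentile 88.44 in mural-like cells. Of its 5 measured members there, 4 had an interval that held 1 and 1 an interval below 1, so the list showed no clear direction in that class. Its median was 0.34 in astrocyte-like cells, 0.50 in oligodendrocyte precursor-like cells, 0.51 in microglia-like cells and -0.02 in thalamus-like neurons. A stronger stress response outside the immediate early genes therefore stays open, and a stronger response in some classes stays untested. A difference between the preparations other than foot shock, such as chamber exposure, cannot be told apart, since there is 1 library per group. A neuronal response to foot shock is a hypothesis.

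Higher Sgk1 in foot shock oligodendrocyte-like cells could come from free RNA, but free RNA held 104 CPM against 1312 CPM in the class, which argues against it. More damaged cells as the whole explanation are argued against by the foot shock cells with a mitochondrial share below the median, where Sgk1 was 16.1 times the control level. Sgk1 was higher in foot shock cells above the median, at 1507 CPM (1422 to 1595) against 1146 CPM (1078 to 1218) below it. Control cells went the same way, at 84.7 and 59.3 CPM with overlapping intervals. A part played by damage therefore stays open. A difference between the preparations cannot be told apart, since there is 1 library per group. A glucocorticoid response of oligodendrocytes is a hypothesis.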
